A study of Zea mays with 15 samples.

How the data were processed

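The arrays measured RNA from the meristem of the seventh internode of greenhouse maize at the jointing stage, with 8 leaves. Per the labels' protocols, 100 seedlings were sprayed with 600 mg/L ethephon, a growth regulator that releases ethylene inside the plant, and 100 with water. Tissue was taken at 0 h without spray and at 24 and 48 h after either spray. Each RNA came from 3 seedlings, was extracted with Trizol, and 200 ng of total RNA was labelled as biotin cRNA with the 3' IVT Express kit. The labels give 3 separate biological replicates in each of 5 groups, 15 Affymetrix maize genome arrays in all. The p-values therefore speak of pools of 3 seedlings within 1 greenhouse experiment, and the number of arrays limits the precision.

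Only the processed table was used. Its values were linear MAS5 signals, per the submitters' processing notes, and the unit recorded for them was intensity, as deposited. The MAS5 version and the scaling target were not given in the sources used here, and detection calls were not used here. The table held 17734 probe sets, 113 of them Affymetrix controls that were used only for quality. Values ran from 1 to 22867.4, and 21 values were exactly 1. All 15 columns were used, 0 were left out.

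Signals were taken to log2 without an offset and without further normalization, because array medians already lay between 297.8 and 370.4. Probe sets whose mean signal over the 15 arrays reached the 40th percentile, 218.3, were kept, which left 10573 of 17621. The filter did not use the groups. A model with 5 group means was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along the mean signal (residual degrees of freedom 10, prior 2.62). Benjamini-Hochberg adjustment was made over the kept probe sets of each comparison, with a threshold of 0.05. The comparisons were ethephon against water at 24 and at 48 h, the difference between those differences (48 h minus 24 h), water at 24 and at 48 h against the untreated 0 h arrays, and water at 48 h against 24 h. Errors beside log2 differences are limma standard errors, and errors beside signals are standard deviations with n = 3. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and figures.

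Gene names came from a table of the genes of each probe set and from maize RefSeq symbols, and no coordinates were used. Exactly 1 gene was paired with 1452 probe sets, which stood for 1108 genes, and 16168 probe sets other than the controls had no name. Among kept probe sets 913 had a name, for 762 genes. Where a gene had several probe sets, the one with the highest mean signal stood for it. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, over those 762 genes, and each list call is given with the adjusted p under an estimated correlation. Of 32 preset lists 23 had a kept gene and 9 had at least 5. Because the tables gave symbols without descriptions, 37 further lists were written after the annotation had been seen and before any test, and 26 of these had at least 5 kept genes. The preset and further lists were adjusted separately within each comparison. Within lists, counts are given over all genes and adjusted over the list alone.

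Named genes followed a rule set before the data were examined, as were the filter, the model, the threshold, the preset lists and most of the alternatives. For the ethephon comparisons it took the 8 largest rises and falls that passed, 2 members of each list with a passing member, and the 4 members with the highest signal among ethylene biosynthesis, ethylene perception, gibberellin and expansin genes. For the other comparisons it took the 5 largest rises and falls that passed, among the probe sets that stood for their genes, so called second probe sets (tub5, LOC541999) were left out. Where none passed, the 5 genes with the lowest p were named and said not to pass. The condition on gene descriptions was dropped, expansins were recognized by symbol, and ethylene biosynthesis genes lay below the filter. Examples inside lists were the members with the lowest p, chosen after the values were seen. What a gene is known to do is general background. The covariate for the 3'/5' index, robust moderation, the fit without the 24 h arrays and the pooled ethephon comparison were added after the data had been seen.

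The pipeline was tested on simulated data with 200 changed probe sets among 10573 in each of 10 draws. At a log2 change of 1 it recovered 40.5% of them with independent noise and 37.6% with the residuals of the real arrays. At a log2 change of 2 it recovered 81.1% and 78.1%. False calls averaged 7.4 and 11.5 per draw. A list of 15 genes shifted by log2 0.5 in independent noise was called in 20 of 20 tests, and other lists in 0 of 380. The simulated genes did not vary together, so these tests do not measure false list calls among correlated genes.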

Results

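Transcripts of growth, hormone and wall genes were measured in the meristem of the seventh maize internode, before spray (0 h) and at 24 and 48 h after ethephon or water. Array quality differed between collection times. The 3'/5' index, the log2 excess of 3' over 5' signal of control transcripts, averaged 1.64 ± 0.78 in untreated arrays, 2.88 ± 0.32 with water and 3.01 ± 0.15 with ethephon at 24 h, and 2.05 ± 0.39 with water and 2.73 ± 0.09 with ethephon at 48 h (n = 3 each). Among untreated arrays the index was 0.743 on the second and 2.01 and 2.17 on the others, so 1 array lowered their mean. The index differences between ethephon and water were 0.128 at 24 h (exact permutation p = 0.7, adjusted 0.7) and 0.683 at 48 h (exact permutation p = 0.1, adjusted 0.167), and 0.1 was the smallest p that 3 against 3 arrays could give. The 5' probe set of the LysX spike read 21.1 to 34.4 on all 24 h arrays and 43.5 to 72.7 on all others. Comparisons between water at 24 h and any other time therefore carried a difference in spike signal, which can come from labelling or from the spike-in stock, while ethephon and water at 24 h shared the low LysX signal. The 5' probe set of the BioB spike differed between these 2 groups, with 654.7 to 756.4 on the ethephon arrays and 471.9 to 523.9 on the water arrays.

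**Figure D1:**
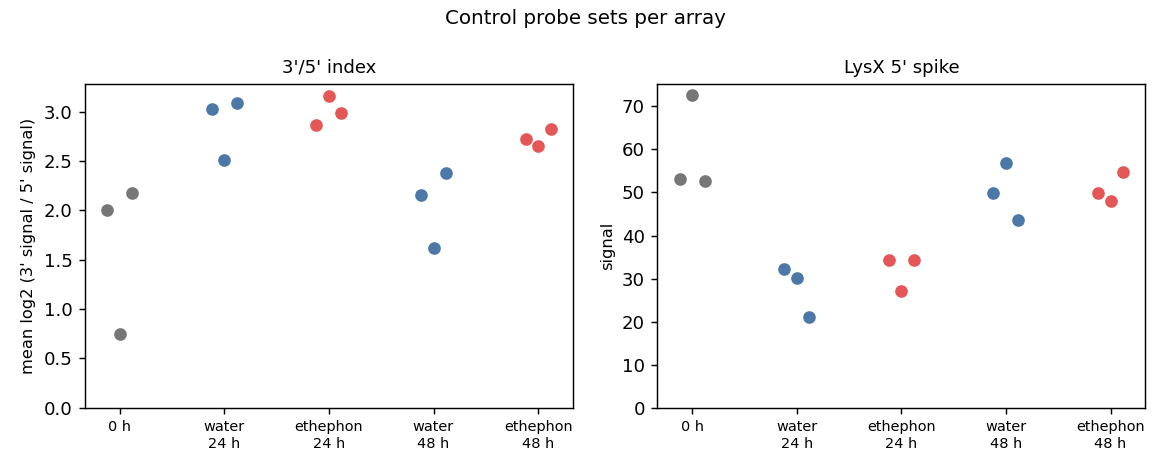
The 3'/5' index and the signal of the 5' LysX spike probe set on each of the 15 arrays.

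Groups overlapped widely. Correlations between arrays of 1 group ran from 0.765 to 0.914 (median 0.862) and between groups from 0.679 to 0.941 (median 0.85), and 0 of 15 arrays had their closest match within their own group. The first principal component held 30.5% of the variance and the second 21.1%.

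At 24 h after ethephon the largest difference of a named gene was that of the glutathione transferase gene gst30, whose signal was 1654 ± 194 with ethephon and 65.2 ± 59.6 with water (log2 difference 5.04 ± 0.87, with 4.59 to 5.75 when 1 array was left out and 4.28 with an offset of 32). The water signal lay below the filter level, so the fold itself is uncertain. The ethylene receptor gene etr2 lay 2.11-fold higher (609 ± 141 against 295 ± 103, log2 difference 1.08 ± 0.29). Higher lay also d3, which encodes the ent-kaurenoic acid oxidase of gibberellin synthesis (506 ± 183 against 153 ± 51.9, log2 1.71 ± 0.37), and the D-type cyclin gene cycD2 (2839 ± 156 against 1718 ± 141, log2 0.73 ± 0.13). Outside the 24 h ethephon arrays the group means of d3, 117.5 to 185.3, lay below the filter level, so its fold is uncertain too. The cytokinin response regulators RR6 (268 ± 114 against 1047 ± 256, log2 -2.02 ± 0.53) and RR7 (147 ± 34.1 against 345 ± 42.9, log2 -1.26 ± 0.28) lay lower. At 0 h the untreated signals were 191 ± 146 for gst30, 368 ± 101 for etr2, 157 ± 41.1 for d3 and 2772 ± 356 for cycD2. Those of RR6 and RR7 were 888 ± 728 and 203 ± 73.4. For cycD2 the ethephon signal lay near that of 0 h and the water signal below both. For RR7 the water signal lay above that of 0 h. Its signals with ethephon and at 0 h lay below the filter level, so the RR7 fold is uncertain too. In each of these 6 genes all 3 ethephon arrays lay beyond all 3 water arrays. All but etr2 were named for their low p in this comparison, so this adds no separate support. None passed limma with Benjamini-Hochberg adjustment over all probe sets: adjusted p = 0.375 for gst30 and cycD2, 0.41 for d3, 0.422 for RR7, and 0.523 for RR6 and etr2.

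**Figure D2:**
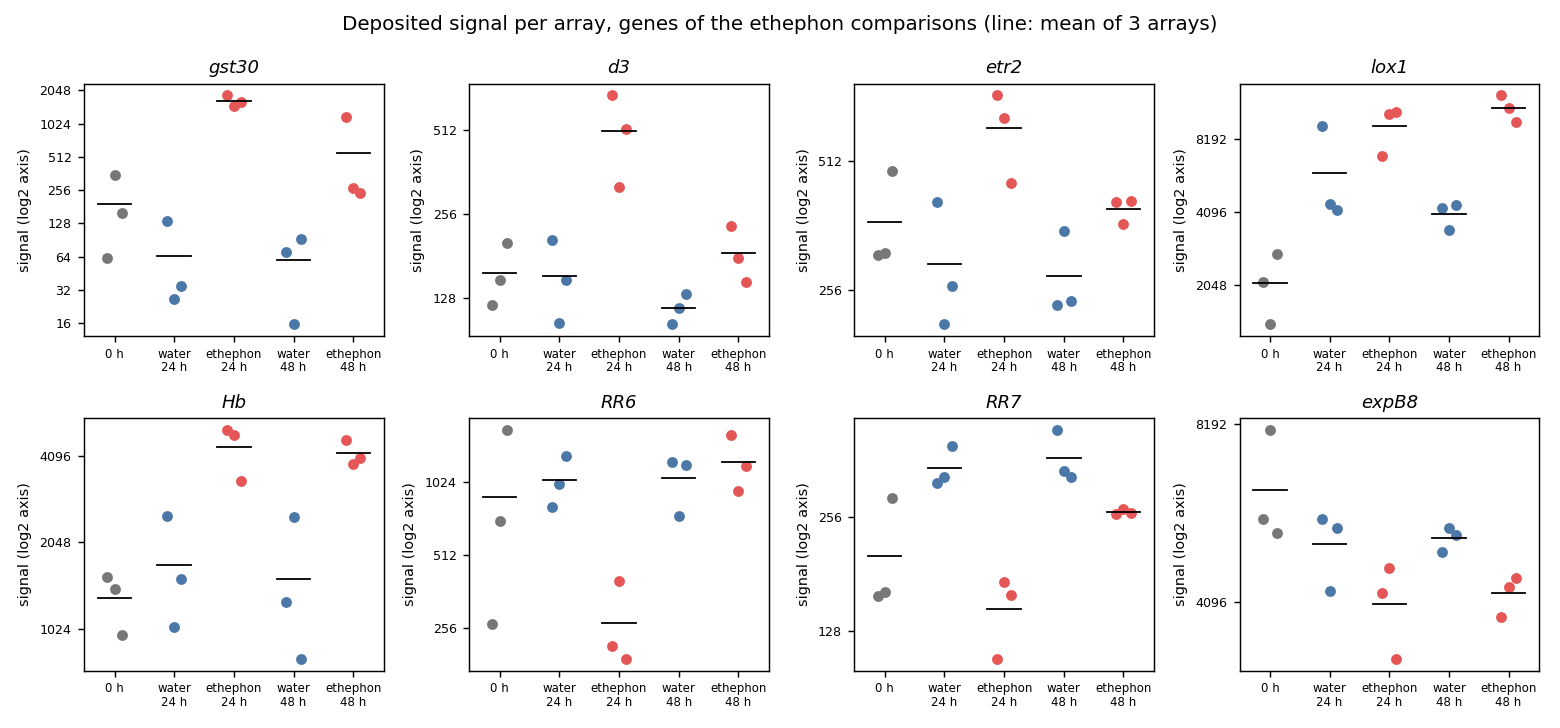
Deposited signal of 8 genes on each array, on a log2 axis, with lines at the mean of 3 arrays.

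Of the expansins, wall-loosening proteins, expB8 had the highest signal and lay slightly lower with ethephon (4060 ± 717 against 5131 ± 748, log2 -0.34 ± 0.17, adjusted p = 0.563), while a second expB8 probe set lay at log2 0.31. The differences were 0.79 ± 0.65 for expB4 (adjusted p = 0.633), -0.18 ± 0.64 for EXPA5 (0.916) and -0.18 ± 1.44 for expB6 (0.966). Genes of ethylene biosynthesis were too weak to test: the ACC oxidase genes ACO20 and ACO31 had mean signals of 120.1 and 114.8. At 24 h ACO31 read 167 ± 11.9 with ethephon and 130 ± 17 with water, and ACO20 82.4 ± 11.8 with ethephon and 133.1 ± 45.1 with water. Among gibberellin genes an1, GA20, KS and CPPS2 also lay below the filter (140.9, 96.9, 34.5 and 22.8).

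The preset list of jasmonate genes was higher with ethephon at 24 h (5 of 6 genes higher, median log2 0.45, camera adjusted p = 0.0491, adjusted p = 0.154 with an estimated correlation, range over alternatives 0.0218 to 0.154). The mean log2 difference of the list was 0.838. Most of that mean, though not of the median, came from opr5 (log2 3.26 ± 1.15, 2293 ± 954 against 429 ± 442), an oxophytodienoate reductase gene without a known part in jasmonate synthesis. The lipoxygenase gene lox1 lay at 0.72 ± 0.30, the allene oxide synthase gene aos1 at 0.52 ± 0.35, and opr8 and opr7, which maize needs for jasmonate, at 0.39 ± 0.21 and 0.34 ± 0.24. The allene oxide cyclase gene aoc1 lay at -0.21 ± 0.24. Of these genes 0 passed, whether adjusted over the list alone or over all genes.

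The other 8 preset lists did not pass at 24 h. Cytokinin genes had a median of -0.26 (adjusted p = 0.158), with RR7, RR6 and RR5 (-1.04 ± 0.36) lower when adjusted over the list alone. The RR5 signal was 351 ± 181 with ethephon, 649 ± 53.8 with water and 264 ± 74.8 at 0 h. Cellulose synthases lay at 0.28 (0.252), aquaporins at 0.22 (0.307), cell cycle genes at -0.60 (0.402), sucrose and starch genes at -0.24 (0.402), redox genes at 0.33 (0.402), tubulins at -0.04 (0.472) and photosynthesis genes at -0.09 (0.708). Lists with fewer than 5 kept genes were not tested as lists. Within them, adjusted over the list alone, the abscisic acid genes vp14 (723 ± 237 against 198 ± 110, log2 1.97 ± 0.56) and rab17 (3.43 ± 1.34), and the wax gene gl1 (2.82 ± 1.09) were higher, and 0 of them passed over all genes. The vp14 signal with water lay below the filter level, so its fold is uncertain. The ethylene perception and gibberellin lists kept 1 gene each, etr2 and d3, so there was nothing to adjust over.

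Of the further lists, abscisic acid and dehydration genes (7 of 8 higher, median log2 0.34, camera adjusted p = 0.037; adjusted p = 0.581 with an estimated correlation) and senescence-associated proteases (5 of 5 higher, median 0.35, adjusted p = 0.037; 0.599 with an estimated correlation) were higher with ethephon. The proteases with the lowest p were see2a (0.89 ± 0.31) and cys2 (0.53 ± 0.21). Ribosomal protein genes were lower (17 of 19, median -0.17, adjusted p = 0.037; adjusted p = 0.72 with an estimated correlation), and the further jasmonate list of 7 genes was higher (adjusted p = 0.037; 0.429 with an estimated correlation). Hemoglobin Hb (log2 1.45 ± 0.39) was higher within the anaerobic response list alone, beside pyruvate decarboxylase pdc3 (0.87 ± 0.32) and alcohol dehydrogenase adh2 (0.78 ± 0.31).

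**Figure D3:**
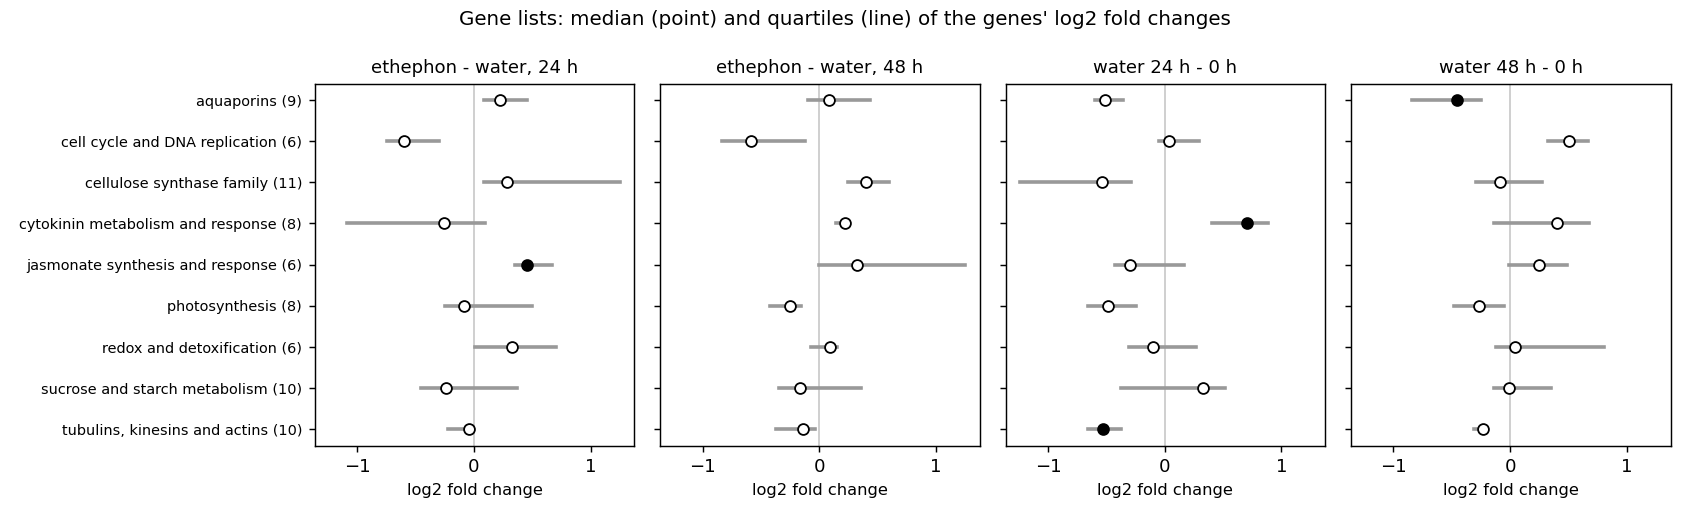
Median and quartiles of the log2 differences of the 9 preset lists in 4 comparisons, with filled points where the camera adjusted p was under 0.05.

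Over all probe sets limma called 0 at 24 h (lowest adjusted p = 0.375), while 951 had an unadjusted p under 0.05 where 529 would arise by chance. With array weights 169 probe sets were called, 131 higher and 38 lower, among them gst30 (log2 5.41, adjusted p = 0.0117), cycD2 (0.0161), etr2 (0.0285), d3 and RR7 (both 0.0424), and in the other settings that left out no replicate the lowest adjusted p lay between 0.183 and 0.515. The ethephon and water arrays did not overlap for 745 probe sets that lay higher and 1141 that lay lower, 17.8% of all against 10% by chance. The calls at 24 h rested on the array weights.

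At 48 h after ethephon lox1 read 11006 ± 1402 with ethephon and 4011 ± 491 with water (log2 difference 1.46 ± 0.30, 2.74-fold), and its second probe set lay at 1.61. Over the settings that left out no replicate the lox1 difference ran from 1.05 to 1.46. The 3'/5' index was higher on all ethephon arrays than on all water arrays at 48 h. Part of the differences at 48 h could therefore come from RNA quality. Hemoglobin Hb (4178 ± 421 against 1521 ± 877, 1.61 ± 0.39), gst30 (560 ± 530 against 59.6 ± 39.7, 3.18 ± 0.87, with 2.39 to 3.67 when 1 array was left out and a water signal below the filter level) and the cystatin gene cpi2 (6824 ± 1541 against 2244 ± 1138, 1.71 ± 0.50) also lay higher, each with 3 of 3 ethephon arrays above all water arrays. The second cpi2 probe set lay at 0.94. The gamma-zein gene gz27 lay at 0.79 ± 0.25, but its other probe set at -0.02. None of these 5 genes with the lowest p passed limma (adjusted p = 0.994 each). They were named for that p, so arrays that do not overlap add no separate support. The ethylene receptor gene etr2 lay at 0.54 ± 0.29 (395 ± 26.1 against 276 ± 64.4) and d3 at 0.64 ± 0.37 (185.3 ± 43.2 against 117.5 ± 14.6, both below the filter level). The expansin expB8 lay at -0.31 ± 0.17 (4231 ± 332 against 5248 ± 248, 3 of 3 arrays lower), but its second probe set at 0.07. The other expansins lay at 0.22 ± 0.65 for expB4, -0.28 ± 0.64 for EXPA5 and -0.79 ± 1.44 for expB6. No named expansin passed.

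No preset list passed at 48 h. Cellulose synthase genes lay higher in 11 of 11 (median log2 0.40, camera adjusted p = 0.0642), jasmonate genes at 0.32 (0.0642, with lox1 higher over the list alone), photosynthesis genes lower in 7 of 8 (-0.25, 0.0725) and tubulins lower in 9 of 10 (-0.14, 0.0725). Cytokinin genes lay at 0.22 (0.233), cell cycle genes at -0.58 (0.354), aquaporins at 0.08 (0.432), redox genes at 0.10 (0.8) and sucrose and starch genes at -0.17 (0.8). Of the further lists, 18 photosynthesis genes were lower (16 of 18, median -0.26, adjusted p = 0.0302; adjusted p = 0.907 with an estimated correlation). Within their own lists alone Hb and cpi2 were higher.

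Limma called 0 probe sets at 48 h (lowest adjusted p = 0.994), also with array weights, and 343 had an unadjusted p under 0.05, fewer than the 529 of chance. Non-overlapping groups were seen for 543 higher and 412 lower probe sets, 9.03% against 10% by chance. With both times pooled, 0 probe sets passed (lowest adjusted p = 0.126) and 1331 had an unadjusted p under 0.05.

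The differences at 24 and 48 h were correlated over all kept probe sets (r = 0.538, Spearman 0.49, 67% with the same sign), but an exact permutation of the array labels over 400 arrangements gave p = 0.09, and without the first ethephon array of 48 h r was 0.153. The middle 95% of the arrangements ran from -0.573 to 0.573. As neither time had a called probe set, an overlap of calls could not be computed.

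The response regulator RR6 had the largest difference between the ethephon responses of 24 and 48 h among cytokinin genes, and no cytokinin gene passed alone. It lay at log2 -2.02 at 24 h and above 0 at 48 h (difference 2.25 ± 0.75), and the type-A response regulators RR5 (1.19 ± 0.51) and RR7 (0.79 ± 0.40) and the receptor kinase HK1 (0.70 ± 0.37) differed the same way. The preset list of 8 cytokinin genes was higher at 48 h relative to 24 h (7 of 8, median 0.51, camera adjusted p = 0.000636; adjusted p = 0.222 with an estimated correlation, range over alternatives 0.000251 to 0.321), and of its members 0 passed, alone or over all genes. For the response regulators the difference lay in the ethephon arrays, as RR6, RR5 and RR7 differed by 0.01, -0.11 and 0.08 between 24 and 48 h of water, while HK1 lay lower at 48 h of water (-0.70 ± 0.26). RR8 (0.17), RR9 (0.20), RR10 (-0.02) and hk2 (0.31) showed little difference.

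Of the further lists, cytokinin genes (13 genes, median 0.28, adjusted p = 0.0277) and chromatin modifiers (40 of 50 higher, median 0.23, adjusted p = 0.0277) were higher at 48 h relative to 24 h. Senescence-associated proteases (5 of 5 lower, median -0.37, adjusted p = 0.0277, with ccp1 at -0.69 ± 0.29 and see2a at -0.64), aquaporins (15 of 19 lower, median -0.27, adjusted p = 0.037) and photosynthesis genes (15 of 18 lower, median -0.18, adjusted p = 0.037) were lower. For all 5 the adjusted p = 0.73 with an estimated correlation. Preset photosynthesis genes lay at -0.29 (adjusted p = 0.0744), aquaporins at -0.17 (0.612), jasmonate genes at -0.12 (0.612), redox genes had an adjusted p = 0.473, tubulins and sucrose and starch genes 0.577, and cellulose synthases and cell cycle genes 0.83. Over all probe sets limma called 0 (lowest adjusted p = 1, 98 with an unadjusted p under 0.05, 0 with array weights). The genes with the lowest p, none passing, were RR6, the aquaporin gene TIP3-1 (-2.35 ± 0.94), ccp1, RR5 and the ferredoxin reductase gene fnr1 (0.83 ± 0.36), all at an adjusted p = 1.

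From 0 h to 24 h after water, genes of thiamine synthesis rose and a chaperone gene fell. The thiazole synthesis genes thi1 (566 ± 538 to 3545 ± 1480, log2 2.96 ± 0.53, 7.80-fold, adjusted p = 0.0132) and thi1-2 (3612 ± 2189 to 10540 ± 2171, 1.69 ± 0.31, 3.23-fold, 0.0149) rose. So did tha9 (403 ± 81.5 to 1369 ± 128, 1.78 ± 0.20, 0.000892), lox1 (2080 ± 666 to 5920 ± 2857, 1.46 ± 0.30, 0.0333) and the chloroplast splicing factor gene rnc1 (274 ± 31.6 to 607 ± 53.1, 1.15 ± 0.21, 0.0138). The ClpB-type chaperone gene hsp101 fell 4.77-fold (3331 ± 1153 to 681 ± 164, -2.26 ± 0.33, 0.00457). The genes rcalm (-0.71 ± 0.13, 0.015), cycD2 (2772 ± 356 to 1718 ± 141, -0.69 ± 0.13, 0.0213), copz2 (-0.64 ± 0.14, 0.0407) and cop2 (-0.63 ± 0.15, 0.0492) fell as well. With 1 array left out tha9 and hsp101 passed in 6 of 6 fits, thi1-2, rnc1 and rcalm in 4, thi1 and cycD2 in 3, lox1 in 2, and copz2 and cop2 in 1. The log2 change of thi1 ran from 2.47 to 3.71 in these fits. With the 3'/5' index as a covariate thi1, thi1-2 and tha9 passed. The calls of lox1 (0.72, adjusted p = 0.795), rcalm (-0.345, 0.728), rnc1 (1.12, 0.49), hsp101 (-2.54, 0.116), cycD2 (0.694), copz2 (0.725) and cop2 (0.736) were lost. In every setting that left out no replicate, the index included, cycD2 lay at -0.552 or below, copz2 at -0.52 or below and cop2 at -0.512 or below. Over all settings that left out no replicate, tha9, thi1 and thi1-2 passed in 10 of 11 and hsp101 in 9 of 11. There lox1, rcalm and cycD2 passed in 8 of 11, rnc1 in 8 of 10, copz2 in 5 of 11 and cop2 in 4 of 11. In every one of these genes all 3 water arrays lay beyond all 3 untreated arrays, which adds no separate support for genes named because they passed. Among probe sets without a gene name, those with the lowest p rose by 4.15 ± 0.30 (adjusted p = 3.17e-05) and changed by -3.15 ± 0.28 (0.000236).

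**Figure D4:**
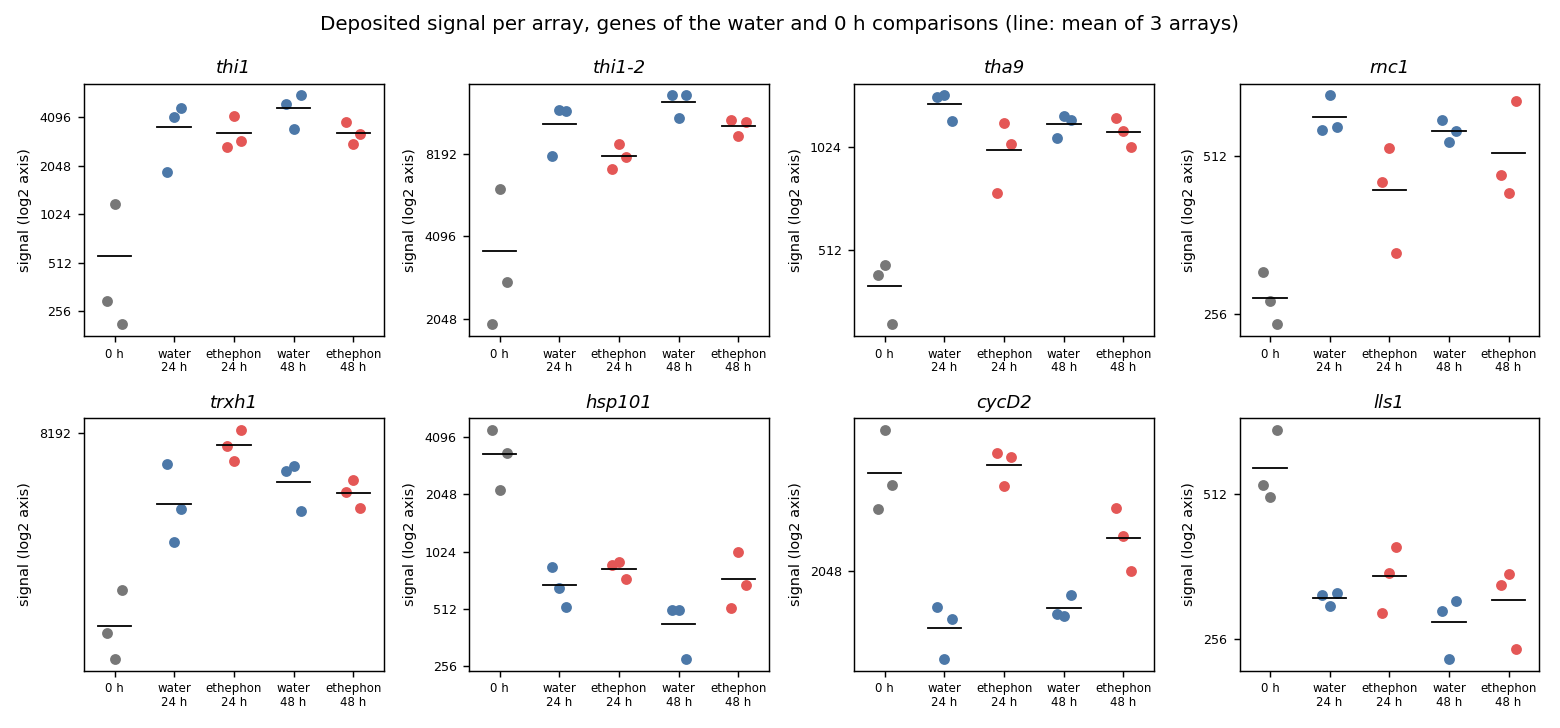
Deposited signal of 8 genes on each array, among them the thiamine and chaperone genes that differed between water and 0 h.

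Tubulin genes were lower at 24 h after water in 10 of 10 (median log2 -0.53, camera adjusted p = 0.000603; adjusted p = 0.412 with an estimated correlation, range 0.000219 to 0.412). Over the list alone 5 passed, TUA1 (-1.29 ± 0.44), tub4 (-1.13 ± 0.38), tub6 (-0.40 ± 0.14), tua4 (-0.26 ± 0.10) and tua5 (-0.63 ± 0.25), and 0 over all genes. A second tub5 probe set, which did not stand for its gene in the list, fell and passed over all probe sets (-2.71 ± 0.62, adjusted p = 0.0486), while the first lay at -0.67 ± 0.28. Cytokinin genes were higher in 8 of 8 (median 0.70, adjusted p = 0.00359; adjusted p = 0.412 with an estimated correlation, range 0.00208 to 0.412). Of these HK1 (0.98 ± 0.26), RR5 (1.33 ± 0.36), RR9 (0.85 ± 0.25) and RR7 (0.82 ± 0.28) passed over the list alone and 0 over all genes. These are a receptor kinase, type-A regulators that restrain the cytokinin response and a type-B regulator that drives it. Photosynthesis genes lay lower in 8 of 8 (-0.48, 0.0832), aquaporins at -0.51 (0.0832), and cellulose synthases lower in 10 of 11 (-0.54, 0.1). Jasmonate genes lay at -0.30 (0.891), redox and cell cycle genes had an adjusted p = 0.558 and sucrose and starch genes 0.907.

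In the small lists, over the list alone, the chaperones hsp101 and hsp22 (-1.41 ± 0.51), and the lignin genes bm1 (-1.37 ± 0.46) and pal3 (-0.60 ± 0.23) were lower. The expansin gene expa1, the only kept gene of its preset list, lay at -1.54 ± 0.60. Of the further lists, aquaporins (16 of 19, median -0.60, adjusted p = 0.0157, TIP2-1 at -2.85 ± 0.86), tubulins and kinesins (14 of 17, -0.46, 0.0157), heat shock proteins (0.0227), photosynthesis genes (17 of 18, -0.44, 0.0227) and lignin genes (6 of 6, -0.99, 0.0275) were lower. Growth-regulating factors and their coactivators (8 of 9, median 0.92, adjusted p = 0.0227, GRF2 at 1.76 ± 0.78), cytokinin genes (0.0298) and ribosomal protein genes (15 of 19, 0.0357) were higher. For all 8 the adjusted p = 0.849 with an estimated correlation.

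Limma called 182 probe sets at 24 h after water, 93 higher and 89 lower, 18 of them named, and 70 and 49 of them by at least 2-fold. With 1 array left out it called 68 to 176, and from the compared arrays alone 11. Non-overlapping groups were seen for 1337 higher and 1161 lower probe sets, 23.6% against 10% by chance. The 24 h arrays had the low LysX signal and an index higher by 1.24 (exact permutation p = 0.1, adjusted 0.167), and with the index as a covariate 13 of the 182 passed, although the log2 changes kept a median of 0.897 of their size (quartiles 0.738 to 1.06) as the median standard error went from 0.216 to 0.301. Water spray, handling and 24 h of growth were not separated by this comparison.

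At 48 h after water thi1, thi1-2, tha9, rnc1 and hsp101 passed as at 24 h, while lox1, rcalm, cycD2, copz2 and cop2 did not. The signal of thi1 rose to 4679 ± 1107 (log2 3.44 ± 0.53 from 0 h, 10.9-fold, adjusted p = 0.00586), thi1-2 to 12632 ± 1353 (1.97 ± 0.31, 0.00711), tha9 to 1193 ± 91.2 (1.58 ± 0.20, 0.0015) and rnc1 to 571 ± 27.8 (1.07 ± 0.21, 0.032). The thioredoxin gene trxh1 rose from 5266 ± 427 to 7319 ± 409 (0.48 ± 0.09, 0.0285). The chaperone gene hsp101 fell 7.70-fold to 430 ± 130 (-2.94 ± 0.33, 0.000847), and lls1, which encodes the pheophorbide a oxygenase of chlorophyll breakdown, fell from 579 ± 102 to 277 ± 39.4 (-1.06 ± 0.21, 0.0402). With 1 array left out lls1 and rnc1 passed in 0 of 6 fits and trxh1 in 2 of 6, while thi1, thi1-2, tha9 and hsp101 passed in 6 of 6. The log2 change of thi1 ran from 2.95 to 4.18 in these fits. All 3 water arrays lay beyond all 3 untreated arrays in each gene, again no separate support for genes named because they passed. Over the settings that left out no replicate rnc1 passed in 5 of 11, trxh1 in 7 of 12 and lls1 in 8 of 11. There thi1-2 passed in 10 of 12, and thi1, tha9 and hsp101 in 11 of 12. The unnamed probe sets with the lowest p rose by 3.80 ± 0.27 (adjusted p = 4.82e-05) and changed by -4.17 ± 0.46 (0.000847).

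Aquaporin genes were lower at 48 h in 8 of 9 (median log2 -0.46, camera adjusted p = 0.0143; adjusted p = 0.608 with an estimated correlation, range 0.00453 to 0.608), with PIP2-1 (-0.84 ± 0.20) and tip1 (-0.46 ± 0.15) passing over the list alone and 0 over all genes. Tubulins lay lower in 10 of 10 (-0.23, 0.0557) and photosynthesis genes in 8 of 8 (-0.27, 0.153). Cytokinin genes lay at 0.41 (0.153, RR5 at 1.22 ± 0.36 and RR7 at 0.90 ± 0.28 higher over the list alone). Jasmonate genes lay at 0.25, cell cycle genes at 0.50 and cellulose synthases at -0.08 (each 0.32), and redox and sucrose and starch genes had an adjusted p = 0.943. Of the further lists, aquaporins (adjusted p = 0.00374, TIP2-1 at -3.29 ± 0.86), heat shock proteins (0.00374, with hsp101, hsp18a at -1.27 ± 0.35, hsp22 at -1.69 ± 0.51 and hsp18f at -1.10 ± 0.41 lower over the list alone), lignin genes (6 of 6, -0.84, 0.0202) and photosynthesis genes (18 of 18, -0.28, 0.0356) were lower. Ribosomal protein genes were higher (16 of 19, median 0.16, 0.0202). For all 5 the adjusted p = 0.937 with an estimated correlation, and over all genes hsp101 alone passed among their members.

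Limma called 84 probe sets at 48 h after water, 39 higher and 45 lower, 8 of them named, and 27 and 37 of them by at least 2-fold. With 1 array left out it called 49 to 68, and from the compared arrays alone 6. Non-overlapping groups were seen for 745 higher and 700 lower probe sets, 13.7% against 10% by chance. With the index as a covariate 62 of the 84 passed. Of the probe sets called at both times after water, 35 were raised at both, 39 were lowered at both and 0 went opposite ways, an overlap to which the shared 0 h arrays contributed. The log2 changes at the 2 times were correlated at 0.743, against 0.497 in simulations in which only the 0 h arrays were shared. A simulated value without a spread cannot show whether 0.743 exceeds chance. Untreated arrays that vary more than water arrays could also raise the correlation.

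Between 24 and 48 h after water tubulin genes were higher at 48 h in 10 of 10 (median log2 0.23, camera adjusted p = 0.00189; adjusted p = 0.341 with an estimated correlation, range 0.00105 to 0.38), TUA1 by 1.05 ± 0.44. Cytokinin genes were lower at 48 h in 6 of 8 (median -0.20, adjusted p = 0.00287; adjusted p = 0.284 with an estimated correlation, range 0.00273 to 0.38), with the receptor kinases HK1 (-0.70 ± 0.26) and hk2 (-0.67 ± 0.34) having the lowest p. The further lists of tubulins and kinesins (adjusted p = 0.0111) and cytokinin genes (0.0166) moved the same ways, with an adjusted p = 0.966 under an estimated correlation for both. Of the members of these lists 0 passed, over the list alone or over all genes. The 24 h water arrays also entered the comparison with 0 h, so an opposite move of lists called there can arise from those arrays alone. Limma called 0 probe sets (lowest adjusted p = 0.992, 344 with an unadjusted p under 0.05, 0 with array weights), and groups did not overlap for 526 higher and 551 lower, 10.2% against 10% by chance. The genes with the lowest p, none passing (adjusted p = 0.999 each), were the tryptophan synthase gene orp1 (-0.47 ± 0.14), aprt1 (0.98 ± 0.29), GAPC2 (0.25 ± 0.08), stm1 (0.42 ± 0.15) and HK1. The index was lower by 0.825 at 48 h (exact permutation p = 0.1, adjusted 0.167), and the LysX signals of the 2 times did not overlap.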

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

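The tests weighed in this section were chosen only after each result was seen, except the splits of the arrays, which were set before.

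Several results ran against what the design would lead one to look for. The cytokinin list changed between 24 and 48 h with an adjusted p = 0.000636 (preset) and 0.0277 (further list), although no gene in that comparison passed and the adjusted p = 0.222 and 0.73 with an estimated correlation. Chromatin modifiers (0.0277), senescence-associated proteases (0.0277), aquaporins (0.037) and photosynthesis genes (0.037) were called there as well, each with an adjusted p = 0.73 under an estimated correlation. The 5' LysX spike averaged 27.8 with water and 32 with ethephon at 24 h, below every array of the other groups. The 3'/5' index averaged 2.88 with water at 24 h and 2.73 with ethephon at 48 h.

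Changes between 0 h and water could have come from RNA degradation or labelling rather than from the plant. With the 3'/5' index as a covariate the called log2 changes kept 0.897 of their size at 24 h (quartiles 0.738 to 1.06, 182 of 182 with the same sign), but only 13 stayed under the threshold as the median standard error went from 0.216 to 0.301, so this remained open. At 48 h they kept 1.01 and 62 of 84 stayed, which argued against it there. The second untreated array lay farthest from its group mean in the index (-0.898), so the covariate fit leans on that array. The covariate was not refitted without it. Probe sets called at 24 h kept 0.815 of their change at 48 h (quartiles 0.645 to 1.01, 181 of 182 with the same sign), on arrays without the low LysX signal. The shared 0 h arrays alone would leave about 0.5 if they varied as much as the 24 h arrays. The index varied more among untreated arrays (standard deviation 0.782) than among water arrays of 24 h (0.321). More than 0.5 could then be left, so the labelling run of the 24 h arrays remained open. Spray, handling and growth over time were not separated by any test.

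Arrays of a group often resembled arrays of other groups more than each other. The axis of this scatter held 37% of the variance within groups. Its correlation with the 3'/5' index was -0.0936 (exact permutation p = 0.804 within groups), which argued against RNA quality as the source of this axis. The rest of the scatter within groups was not compared with the index. Photosynthesis genes had a median correlation of 0.389 with it, so a varying share of green tissue remained open. Wall and lignin genes lay at 0.693 and division and growth genes at -0.763, a gap of 1.46. These lists lay at the ends of the axis and were compared after that was known, so a varying share of maturing against dividing cells remained open as well.

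The cytokinin change between 24 and 48 h could have come from array quality. A labelling difference shared by the arrays of a time cancels in this comparison, where the mean of the 8 genes was 0.698 ± 0.252. One that differs between the ethephon and water arrays of a time does not cancel. The 5' BioB spike differed between them at 24 h, so labelling of that kind remained open. With the index as a covariate the mean was 0.523 ± 0.223, which left RNA quality open. An exact permutation over 400 relabellings within times gave p = 0.01, with a mean of -0.538 at 24 h and 0.16 at 48 h, but the list was picked because it had been called, so chance remained open.

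The arrays were also split into groups that mixed the conditions, and 10 splits are too few for a share under 0.05. For ethephon at 24 h the real split called 0 probe sets and the highest other 0 (10 of 10 splits at or above the real count), and for lists 1 against 2 (5 of 10). At 48 h it called 0 probe sets against 2 (10 of 10) and 0 lists against 4 (10 of 10). For water at 24 h it called 182 probe sets against 0 (1 of 10) and 2 lists against 4 (6 of 10). For water at 48 h it called 84 against 1 (1 of 10) and 1 list against 4 (8 of 10). For water between 24 and 48 h it called 0 against 1 (10 of 10) and 2 lists against 3 (4 of 10). For the change of the ethephon difference with time 100 of 100 splits reached the 0 called probe sets (highest 2) and 67 of 100 the 1 called list (highest 5), so chance could not be excluded for that list.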

How the results depend on the processing

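The tests with the 3'/5' index as a covariate, with robust moderation and without the 24 h arrays were chosen only after the results were seen. For ethephon at 24 h array weights gave 169 called probe sets in place of 0, and leaving out 1 array gave 0 to 2. At 48 h leaving out gave 0 to 1, for the change with time 0 to 1 and for water between 24 and 48 h 0 to 2, each highest without the first water array of 48 h. The 182 calls of water at 24 h became 96 with a replicate block, 11 from the compared arrays alone, 326 with array weights, 13 with the index and 68 to 176 with an array left out (68, 87 and 107 without a water array of 24 h, 79 without the second untreated array), and 145 to 243 otherwise. Median centring gave 168, with 69 higher and 99 lower in place of 93 and 89. The 84 calls of water at 48 h became 62 with the block, 6 from the compared arrays, 189 with array weights, 42 without the 24 h arrays and 49 to 68 with an array left out (49 and 51 without the first or second water array), and 57 to 88 otherwise. The 7 called preset lists became 14 without the filter, 0 under an estimated correlation, 1 with fry and 6 to 10 otherwise. The correlation of the ethephon differences at 24 and 48 h ran from 0.153 (without the first ethephon array of 48 h) to 0.703 with an array left out and from 0.486 to 0.548 otherwise. Signs turned for expB6 at 24 h (0.0098 with an offset of 32, 0.722 with array weights, -1.28 to 1.69 with an array left out), EXPA5 at 24 h (-0.765 to 0.269), expB4 at 48 h (-0.296 to 1.03) and EXPA5 at 48 h (0.551 with the index, -0.669 to 0.389 with an array left out). At 24 h after water lox1 went from 1.46 to 0.719 and rcalm to -0.345 with the index. The cause was not tested for any of these. Replicate numbers did not pair: residuals of arrays with the same number correlated at -0.149, -0.357 and 0.0719 at 24 h and at -0.384, 0.289 and -0.451 at 48 h. Named-gene results, those above included, stayed the same in 475 cases, were weaker in 48, stronger in 5 and reversed in 3 across settings, and with an array left out 269 stayed, 42 were weaker and 7 reversed. A gene that had not passed counted as the same when it kept its sign and again did not pass. All weaker cases were lost calls, so the counts that stayed overstate how stable the calls were. List results stayed in 50 cases and were weaker in 17.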

Other observations

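The tests of the jasmonate genes and of the scatter within groups were chosen only after the results were seen.

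The heat shock genes followed the scatter within groups as well as the time after spray: their median correlation with the axis was -0.639, beside -0.771 for ribosomal protein genes, -0.755 for growth-regulating factors and -0.531 for chromatin modifiers. On the other side lay senescence-associated proteases (0.778), cellulose synthases and COBRA-like genes (0.707), lignin genes (0.636) and aquaporins (0.484). The lists of ribosomal proteins and senescence-associated proteases, called between ethephon and water at 24 h, were among those with the strongest scatter, and both lost the call with an estimated correlation (adjusted p = 0.72 and 0.599). Whether the calls of these lists reflect which part of the internode was sampled was not tested. The axis was computed after the group means were removed, so it cannot show a difference between ethephon and water arrays.

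Of the jasmonate genes lox1, opr5 and aos1 lay higher with ethephon at both times, while opr7 and opr8 lay at 0.34 and 0.39 at 24 h and at -0.01 and 0.02 at 48 h, and aoc1 at -0.21 and -0.10. The list, called at 24 h, did not pass on the separate arrays of 48 h (camera adjusted p = 0.0642), so a rise at both times remained open. Without opr5 and lox1 the mean over both times was 0.198 (exact permutation p = 0.01, for a list picked for its call). At 48 h the 3'/5' index was also higher with ethephon (2.73 against 2.05), so RNA quality remained open for lox1 there. A hypothesis is that ethephon raises lipoxygenase and opr5 transcripts in the internode more than those of opr7 and opr8. Measuring jasmonates and the transcripts of opr5, opr7 and opr8 in more pools per time would test it.

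The thiamine genes thi1 and thi1-2 rose in both comparisons of water with 0 h, while hsp101 fell. With the index as a covariate the 24 h calls had 0.897 of their size but only 13 of 182 passed, and the 48 h calls had 1.01. At 24 h thi1 and thi1-2 still passed with the index (log2 4.20 and 2.46), but from the compared arrays alone they did not (adjusted p = 0.144 and 0.159), and hsp101 lay at -2.54 but did not pass (0.116). The pattern may stem from the warmth or light of the day of collection, which was not tested. A set of unsprayed plants at 24 and 48 h would separate spray from time, but not warmth or light from growth. Such plants were not analysed here.

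The ethylene receptor gene etr2, gst30 and d3 lay higher with ethephon at both times and passed at 24 h only with array weights (log2 1.34, 5.41 and 1.59). As etr2 is an ethylene-responsive receptor gene in other plants, its higher signal could be the direct response to the ethylene released. Whether it is direct was not tested, and an inhibitor of ethylene perception given with ethephon would address it.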
